A study of Mus musculus with 13 samples.

How the data were processed

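The series measured polyadenylated RNA from the nuclei and cytoplasms of mouse oocytes that had, or had lost, the RNA helicase MTR4. Per the labels, each library was made with Smart-seq2, a low-input method that copies RNA from its poly(A) tail, from 10 nuclei or 10 cytoplasms that had been separated by micromanipulation. The labels list 13 libraries. WT nuclei and WT cytoplasms at day 14 have 2 libraries each, WT nuclei at day 21 have 3, and WT cytoplasms at day 21 have 2. MTR4-null nuclei and MTR4-null cytoplasms, all at day 21, have 2 libraries each.

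The submitters' processing notes name TopHat2 2.1.1, Cufflinks 2.2.1 and the genome build mm9, without saying what each was used for or with which settings. The table used here was deposited as FPKM by its name, with 23235 gene symbols and 4 columns, 1 for each genotype and compartment. It holds no column for a single library. The 2 null columns were taken as the authors' values for the day 21 null groups of 2 libraries each, though the digits of the null cytoplasm column, described next, read as a single value, so that it may hold 1 library. The WT columns name no day, so it is unknown whether they hold day 14 libraries, day 21 libraries or both. Genotype and age are therefore not separable in any comparison of null with WT.

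The values were treated as a score, because the deposited columns are not on 1 common FPKM scale: their totals run from 594034 in the WT nucleus to 6637350 in the WT cytoplasm. The digits were examined for values from 20 to below 90000. A mean of 2 values printed with 6 digits has at most 7 digits once doubled. In the WT nucleus 87.6% of values met this after division by 0.125, against 23.5% without it. In the null nucleus 97.6% met it after division by 0.5, against 74.6% without it. In the WT cytoplasm 99.9% met it with a factor of 1, but the digits of that column hardly told 1 from 0.5. Each null cytoplasm value could be read as a single number of at most 6 digits multiplied by 0.5 (100% of values, against 64.5% with a factor of 1). All of them also met the rule for a mean of 2 with a factor of 1. However, once doubled, 100% had at most 6 digits, against 71.5% in the WT cytoplasm, so the reading as a single value was used. Such digits fix a factor only up to a power of 10, and only for the number of values taken as averaged. Means of more than 2 values were not examined, though the WT columns may hold more than 2 libraries each. A mean of more values with another factor can give the same digits. How the columns were averaged or scaled is not given in the sources used here, nor is the sequencing depth in reads. The symbols hold 26 entries that are plain numbers, as a spreadsheet makes of date-like names, and these were left as they stand.

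A limma fit over 13 libraries had been planned before the data were examined. With 1 column per genotype and compartment there was no spread between replicates, so that no p-value, standard error or standard deviation could be given, and the gene set test camera could not be run either. The planned comparisons of day 21 with day 14 could not be made. In their place, differences were described by size. Genes with a value of at least 1 in at least 2 of the 4 columns were kept (14240 genes), 1 was added, and differences were taken on the log2 scale, which understates the change of low genes. A gene was counted as higher or lower when it differed at least 2-fold on that scale. The filter used the null columns too: a gene under 1 in both WT columns was kept only with both null columns at least 1. Genes low in WT were thus kept in part for being high in null, and the reverse for genes low in null. All values were used as deposited and, as an alternative chosen before the data were examined, after each column had been divided by its median ratio to the geometric mean column (genes above 0 in all 4 columns). The divisors were 0.279 for the WT nucleus, 0.594 for the null nucleus, 3.47 for the WT cytoplasm and 1.85 for the null cytoplasm. Differences on this second scale are called relative below. They describe a gene against the median gene and cannot show a change in total RNA.

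Gene lists had been fixed before the data were examined: 26 lists, of which 23 had at least 5 kept members. Each list's median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these columns. That mean was taken over all columns, the null columns included, so the WT level alone was not held fixed. For long noncoding RNA genes, null against WT in the nucleus, random lists had a median of 0.26 with such matching. With matching on both WT columns it was 0.56. The fixed lists were not matched on the WT columns alone. A list was called apart when its median lay outside the percentiles 2.5 to 97.5 on both scales. Asking for both scales was decided after the values were seen. Rescaling moves a list and its random lists alike, so the scales differ here only through the added 1 and the random draw. In each comparison 1.15 of 23 lists would lie outside on a single scale by chance if lists were random draws. The step was also run on simulated data for 14240 genes, with lists of 25 genes and on the rescaled columns alone. In the nucleus it placed 169 of 200 lists outside the percentiles when every member was changed 2-fold. It placed 88 of 200 outside at 1.5-fold and 10 of 200 with no change. For the cytoplasm it placed 178, 97 and 6 of 200 outside. The differences had been shuffled over genes, which removed any trend with expression and any correlation within lists. These rates are therefore not those of the rule on both scales, and cannot show whether the matching works.

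The planned rule for named genes asked for an adjusted p and non-overlapping libraries, which could not be applied. The rest of the rule was kept. Genes were ranked by the log2 difference as deposited, with a value of at least 5 in the higher column and at least 0.001 in every compared column, and provisional symbols were left out. The first 8 each way were named for null against WT and for nucleus against cytoplasm in WT, and the first 5 each way for the other comparisons. Small RNA genes, taken by symbol, were also left out of this ranking, a choice made after the values were seen. Their lengths, apart from that of Rn45s, lie below what the method measures well. Up to 4 members of each list were taken by the size of the relative difference.

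RefSeq gene types were matched to 22997 of the symbols (99.0%) by symbol or synonym. Exon number and transcript length came from the longest GENCODE transcript, matched for 98.6% of kept genes. That annotation is for GRCm38 and the table is for mm9, so it served for gene structure and sequence only, and no coordinates are given. Alternatives were a pseudocount of 0.1, no filter on low values, a mean of at least 5, median-ratio rescaling and quantile normalization. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.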

Results

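The table held 1 value per gene for WT nuclei, MTR4-null nuclei, WT cytoplasms and MTR4-null cytoplasms of mouse oocytes. MTR4 is the helicase that feeds nuclear RNA to the exosome, the main 3' to 5' RNA-degrading complex of the nucleus. No column had a replicate, so no difference below could be set against the spread between libraries, and the day of the WT oocytes is unknown. Column totals were 594034 in the WT nucleus, 1396110 in the null nucleus, 6637350 in the WT cytoplasm and 3007240 in the null cytoplasm, and read depth is unknown. The gene with the highest value was Snora47 in both nuclei, Gm15698 in the WT cytoplasm and Mir484 in the null cytoplasm. Small RNA genes took 21.2% of the total in the WT nucleus, 17.9% in the null nucleus, 2.65% in the WT cytoplasm and 6.85% in the null cytoplasm. The class was taken by symbol and includes Rn45s, a long ribosomal RNA precursor. Rn45s alone held 0.487%, 0.913%, 0.401% and 0.943% of the totals, in the same order. Across kept genes, the Spearman correlation was 0.909 between the WT columns, 0.907 between the null columns, 0.836 between the nuclei and 0.816 between the cytoplasms; genes are not independent replicates.

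Skiv2l2, the gene that encodes MTR4, had a value of 13.3 in the WT nucleus and 3.54 in the null nucleus. In the cytoplasm its value was 187 in WT and 4.36 in null. The targeted gene was thus lower in both null columns. Relative to the median gene, the log2 difference was -2.81 in the nucleus and -4.03 in the cytoplasm.

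The first comparison asked which RNAs differed between null and WT nuclei. Mt1, a metallothionein that binds metal ions, had the highest difference among the ranked genes, from 2.82 in WT to 2208 in null. Snhg9, a host gene of small nucleolar RNAs, went from 27.3 to 2075, and the histone H4 gene Hist1h4i from 0.700 to 110. The other genes named as higher were Klhdc9 (2.56 and 428), Prr15l (0.114 and 102), Zfp799 (8.61 and 467), Gin1 (0.439 and 66.4) and Cyp2c53-ps (0.553 and 70.7). Those named as lower in null were Anxa5, an annexin (59.7 and 1.06), the ribosomal protein gene Rps27 (153 and 4.51), Rgn (35.6 and 0.736), Tekt4 (20.3 and 0.129), Bfsp1 (33.4 and 0.935), Dcpp2 (20.1 and 0.354), Tuba3b (50.4 and 2.68) and Agpat9 (22.8 and 0.977). Reads of Rps27, Tuba3b, Dcpp2 and the histone genes can be split with near-identical copies, so these values are uncertain.

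Of the 23 fixed lists, 5 stood apart in the nucleus. Whether these lists would stand apart under matching on the WT columns alone was not tested. Counts of list members are relative to the median gene unless given as deposited. Of 68 replication-dependent histone genes in the table, 37 passed the filter on low values. Members under 1 in both WT columns are among the 37 only if both null columns reached 1. Of the 37, 21 were at least 2-fold higher in null relative to the median gene and 1 was lower (28 and 0 as deposited). The list's relative median of 1.32 lay at percentile 99.98 of random lists. Because the libraries were copied from poly(A) tails, the histone values here and in the cytoplasm cover polyadenylated RNA only. They cannot show a change in total histone RNA. Hist2h4 had 2.51 in WT and 135 in null, Hist1h4c 3.80 and 104, and Hist4h4 1.20 and 22.8. Of 15 nuclear-retained long noncoding RNAs in the table, 10 were kept under the same filter. Of these 10, 8 were higher and 0 lower, also as deposited (relative median 1.38, percentile 97.9). Malat1, an abundant RNA of nuclear speckles, had 22.7 and 364, Xist 0.528 and 9.37, Airn 2.58 and 18.4, and Kcnq1ot1 2.08 and 13.6. Of 19 snoRNA host genes, 9 were higher and 3 lower (12 and 0 as deposited, relative median 0.63, percentile 99.4), with Snhg4 at 0.124 and 44.6, Snhg12 at 0.326 and 15.1 and Snhg3 at 8.70 and 140. Cytoplasmic ribosomal protein genes had a relative median of -0.037, at percentile 99.9, above random lists of like expression, whose median was -0.39. Of these 79 genes, 1 was higher relative to the median gene, Rpl9 (27.0 and 182), and 1 was lower, Rps27, while as deposited 42 were higher and 1 lower. Of 27 genes of meiotic resumption and the cell cycle, 13 were lower and 2 higher (relative median -0.82, percentile 0.17), against 1 lower and 5 higher as deposited. Cyclin B3 (Ccnb3) had 11.1 and 4.91, Mad2l1 132 and 88.0, the kinase gene Aurka 178 and 119, and Btg4 1342 and 926. The other 18 lists had relative medians from -0.55 to 0.11.

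As deposited, 6590 of 14240 genes were at least 2-fold higher in the null nucleus and 526 were lower, with a median log2 difference of 0.91. After median-ratio rescaling 3668 were higher and 2309 lower. Among called genes the share that was higher went from 92.6% to 61.4%. Under quantile normalization 2846 were higher and 2844 lower. With the factors read from the digits divided out the direction turned, with 2193 higher and 6152 lower. The balance of higher and lower genes thus rests on the scale of the columns.

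**Figure D1:**
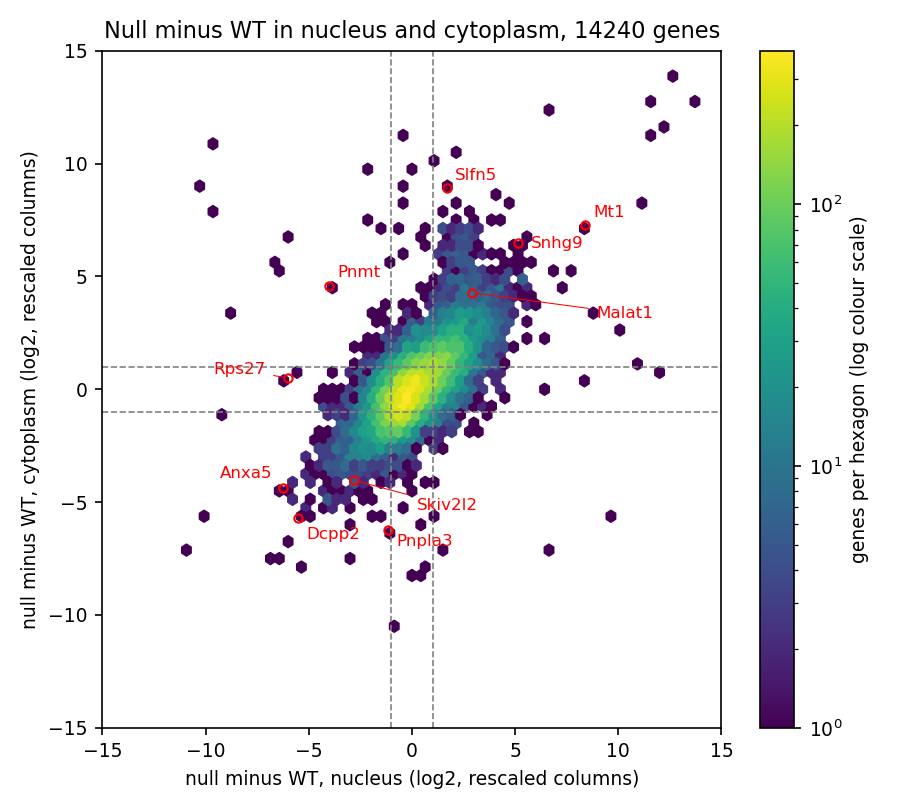
Null minus WT log2 differences after median-ratio rescaling, nucleus on the horizontal axis and cytoplasm on the vertical axis, for 14240 genes. Colour gives the number of genes per hexagon on a log scale, dashed lines mark 2-fold and red circles mark 10 named genes. Most genes lie along the rising diagonal, with a Pearson correlation of 0.665 across genes.

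The second comparison asked the same of the cytoplasm. The genes named as higher in null were Irf9, a transcription factor of the interferon response (0.711 in WT and 605 in null), Slfn5 (11.1 and 3724), Ccdc48 (5.60 and 1686), Rplp2-ps1 (9.49 and 1779), Tapbpl (4.59 and 937), Cyp2e1 (1.95 and 362), Lrrc2 (36.5 and 4332) and Cd300a (6.35 and 729). All 8 also belonged to a set of 303 genes whose relative value was at least 4-fold higher in the WT nucleus than in the WT cytoplasm, a column this comparison also uses. The set leaves out small RNA genes and genes under 5 in the WT nucleus as deposited. Transcripts of 6 of the 8 held a 25-base stretch of the B2 repeat. The genes named as lower were Pnpla3, a lipase gene (1944 and 12.1), Oas1f (866 and 5.69), the chemokine receptor gene Cxcr3 (202 and 0.689), Dcpp2 (529 and 3.57), Tmsb15b2 (109 and 0.00421), Tuba3b (535 and 4.26), Agbl2 (133 and 0.445) and Glis1 (300.2 and 2.51). Mt1 had 45.1 in WT and 3973 in null, and Malat1 had 9.83 and 136; these were added because of their values in the nucleus. Rplp2-ps1 is a pseudogene that can share reads with its parent gene.

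In the cytoplasm 4 lists stood apart. Here too, matching on the WT columns alone was not tested. Of 37 histone genes, 20 were at least 2-fold higher relative to the median gene and 4 lower (17 and 7 as deposited, relative median 1.02, percentile 99.8), among them Hist1h2ag (1.22 and 32.4), Hist4h4 (12.6 and 82.1), Hist2h3c1 (9.37 and 54.9) and Hist1h4b (5.90 and 39.3). Of 19 snoRNA host genes, 8 were higher and 2 lower (relative median 0.54, percentile 98.3), against 8 and 7 as deposited. Snhg9 had 210 in WT and 10043 in null, Snhg3 had 20.9 and 1368, Snhg7 had 2.72 and 67.4, and Snhg11 had 1.44 and 73.1. Of 52 genes of the spliceosome and splicing factors, 11 were higher and 3 lower (relative median 0.20, percentile 99.85), against 3 higher and 18 lower as deposited, with Luc7l2 at 78.0 and 3696, Srsf9 at 131 and 364, Sf3a2 at 54.1 and 109 and Prpf4 at 19.9 and 42.2. Of 27 meiotic genes, 11 were lower and 2 higher (21 and 0 as deposited, relative median -0.83, percentile 1.58); Ccnb3 had 63.8 and 4.67, Plk1 2040 and 275, Cdc20 1716 and 231, and Aurka 2932 and 428. Of the members named here, Luc7l2, Sf3a2, Snhg3, Snhg7 and Snhg11 belonged to the set higher in the WT nucleus, which is chosen for low WT cytoplasm values. Luc7l2 and Snhg11 also held the B2 stretch. The other 19 lists had relative medians from -0.51 to 1.09, the highest being that of the nuclear-retained long noncoding RNAs.

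As deposited, 2121 genes were at least 2-fold higher in the null cytoplasm and 6225 lower, with a median log2 difference of -0.79. After rescaling 3440 were higher and 2653 lower, and the share of called genes that was higher went from 25.4% to 56.5%. The relative difference was at least 2-fold higher in both compartments for 2332 genes, against 886 for independent lists of those sizes, and at least 2-fold lower in both for 1199, against 430. These comparisons share no column, but both differences followed the WT cytoplasm value. Genes without the B2 stretch had relative medians of 1.14 in the nucleus and 0.95 in the cytoplasm where the WT cytoplasm value was under 5. Where it was at least 200, the medians were -0.45 and -0.63. Part of this trend is built in, since the cytoplasmic difference subtracts the WT cytoplasm value. The filter also kept genes under 1 in both WT columns only with both null columns at least 1. How much of the trend is left beyond this was not tested. Independent lists hold no such shared trend, so the excess over them does not show agreement gene by gene. If the WT columns hold oocytes of another day than the null columns, a difference of age would be shared by both.

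**Figure D2:**
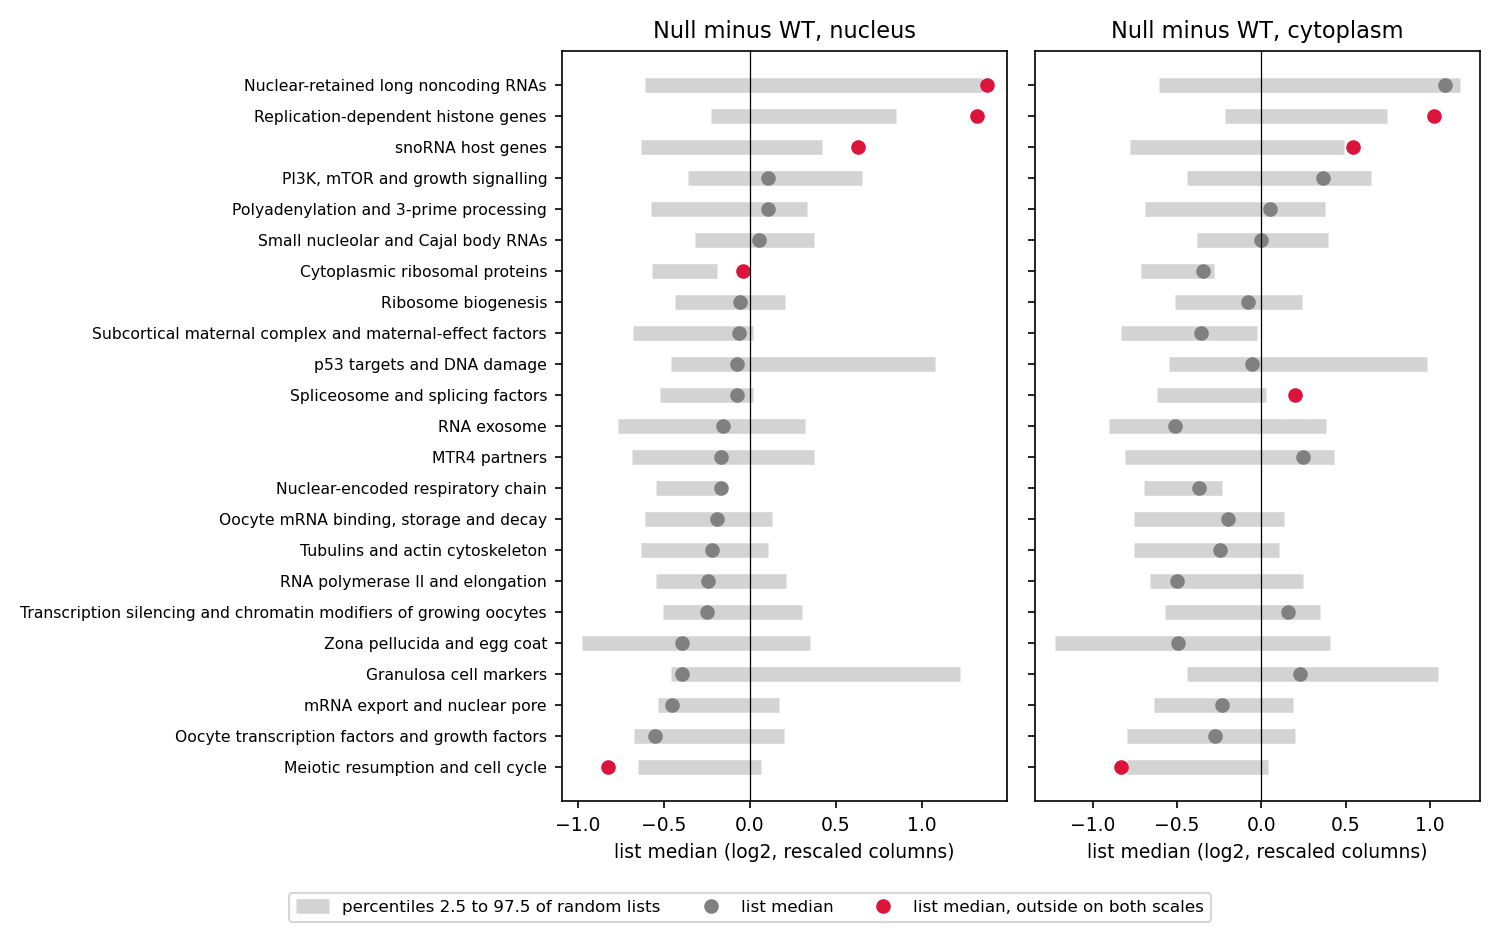
Median null minus WT log2 difference (rescaled columns) of the 23 fixed lists in nucleus and cytoplasm. Grey bars span the percentiles 2.5 to 97.5 of 10000 random lists matched on mean expression over all columns. Red points mark lists outside on both scales, such as the histone genes at 1.32 and 1.02.

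The nucleus was compared with the cytoplasm in WT to see which transcripts each compartment held. As deposited most genes had a higher value in the cytoplasm, the median gene by 13.5-fold, a size that rests on the column factors: the median log2 difference was -3.27 as deposited and -0.71 with the factors read from the digits divided out, or -1.67 if the factor of the WT cytoplasm was 0.5 and not 1. Highest in the nucleus among the ranked genes were Rplp2-ps1 (273 in nucleus and 9.49 in cytoplasm), Eif3j (15.7 and 0.0422), Slfn5 (168 and 11.1), Loxl2 (494 and 37.2), Xaf1 (224 and 18.6), Tapbpl (55.5 and 4.59), Churc1 (1310 and 139) and Cxcr2 (461 and 49.1), and transcripts of 5 of these 8 held the B2 stretch. Lowest in the nucleus were Apoo-ps (11.2 and 1110), Bex4 (0.635 and 144), Inha, the inhibin alpha subunit of granulosa cells (1.92 and 253), Grb7 (1.23 and 169), Id3 (2.35 and 237), Ldhc (5.57 and 427), Tgif1 (1.77 and 163) and Scgb3a1 (0.153 and 61.3). The 7 lists apart were small nucleolar and Cajal body RNAs, nuclear-retained long noncoding RNAs, MTR4 partners, snoRNA host genes, chromatin modifiers, spliceosome genes and oocyte mRNA storage genes, and each was higher in the nucleus than its random lists. As deposited, all of them but the small RNAs had more members lower than higher in the nucleus. Of 114 small nucleolar and Cajal body RNAs in the table, 57 were kept. Of these 57, 53 were higher in the nucleus (48 as deposited, relative median 8.31), with Snora47 at 19857 and 1753. Because the libraries were copied from poly(A) tails, values of these RNAs, here and in the other comparisons, cover polyadenylated RNA only. Their lengths also lie below what the method measures well. Of 741 small RNA genes in the table, 129 had a value of at least 0.001 in the WT nucleus and 56 in the WT cytoplasm. Where the cytoplasm had 0, the added 1 sets the difference, so its size is uncertain. Malat1 had 22.7 in nucleus and 9.83 in cytoplasm, and the snoRNA host gene Snhg11 had 11.3 and 1.44.

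Some genes of these lists had lower values in the nucleus as deposited but were higher relative to the median gene. Pabpn1, a nuclear poly(A)-binding protein gene, had 45.8 in nucleus and 225 in cytoplasm (relative log2 difference 1.33). The same held for Hnrnpu (79.0 and 372, relative 1.39), Lsm14b (83.3 and 448, relative 1.20) and Suz12 (58.4 and 347, relative 1.06). As deposited 248 genes were at least 2-fold higher in the WT nucleus and 12990 lower, after rescaling 1385 were higher and 1062 lower, and with the factors divided out 961 were higher and 4878 lower, or 621 and 10881 with 0.5 for the WT cytoplasm.

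In the null oocytes the median gene was 3.13-fold higher in the cytoplasm as deposited. This size also rests on the column factors: the median log2 difference was -1.48 as deposited, -0.0086 after rescaling and -1.56 with the factors divided out. Pola2, a DNA polymerase alpha subunit gene, had 23006 in the nucleus and 740 in the cytoplasm, and Tspan15 had 1459 and 106. Cort (44.1 and 1.65), Il11 (44.4 and 1.95) and Olfr856-ps1 (90.8 and 6.39) followed, and all 5 belonged to the set higher in the WT nucleus. Lowest in the nucleus were Rps27 (4.51 and 1832), Akr1b3 (0.00269 and 83.4), Pnmt (0.250 and 87.7), Igfbp5 (0.0303 and 30.7) and Tmsb4x (1.55 and 65.4). Lists apart were 4 in number. Of 57 small nucleolar and Cajal body RNAs 49 were higher in the nucleus (43 as deposited), Snora47 at 38257 and 2673 among them, and 6 of 19 snoRNA host genes were higher and 2 lower (1 and 9 as deposited), with Snhg8 at 23.2 and 10.8. The p53 target list was lower in the nucleus than its random lists (relative median -0.58, percentile 0.38), though only 2 of 18 members were at least 2-fold lower, 0 were higher and 16 lay between (14 lower and 0 higher as deposited), with Sesn2 at 0.349 and 6.12 and Perp at 0.642 and 7.42. So were markers of granulosa cells, the somatic cells around the oocyte (relative median -0.87, percentile 0.02), of which 7 of 17 were lower and 1 higher (14 and 0 as deposited), with Hsd3b1 at 0.956 and 42.0 and Wt1 at 0.327 and 16.4. Granulosa markers summed to 0.0294% of the total in the WT nucleus, 0.0178% in the null nucleus, 0.0442% in the WT cytoplasm and 0.0316% in the null cytoplasm. As deposited 415 genes were higher in the null nucleus and 10235 lower, and after rescaling 1771 were higher and 1258 lower.

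The last comparison asked whether the nuclear share of a transcript differed between null and WT. The nucleus minus cytoplasm difference was higher in null for Pnpla3, Grb7, Wdfy1, Ifngr2 and Tmsb15b2, with relative log2 values of 5.08, 4.59, 4.13, 4.74 and 3.12 in that order. It was lower for Pnmt (-8.62), Eif3j (-6.55), Slfn5 (-7.22), Irf9 (-5.87) and Rplp2-ps1 (-6.62), all 5 of the set higher in the WT nucleus, which is chosen on the WT difference that this comparison subtracts. Ifngr2, an interferon gamma receptor gene, had 0.988 in the WT nucleus and 60.8 in the null nucleus against 9.76 and 4.15 in the cytoplasms. Of the lists, 2 stood apart, both with medians below the percentile 2.5 of random lists. The 16 MTR4 partner genes had a relative median of -0.56 (percentile 1.40), with 3 lower, 0 higher and 13 within 2-fold, Papd5 at -1.72 and Rbm7 at -1.59 among the lower, while as deposited 12 were higher and 0 lower. The 57 small nucleolar and Cajal body RNAs had -0.28 (percentile 1.36) with members going both ways, 22 lower, such as Snora21 at -3.63, and 19 higher (15 and 24 as deposited). After rescaling 2412 genes had a difference at least 2-fold higher in null and 2174 at least 2-fold lower, against 10204 and 473 as deposited. With the factors divided out 784 were higher and 6453 lower, or 2736 and 2488 with 0.5 for the WT cytoplasm, so the direction of this difference is not known.

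**Figure D3:**
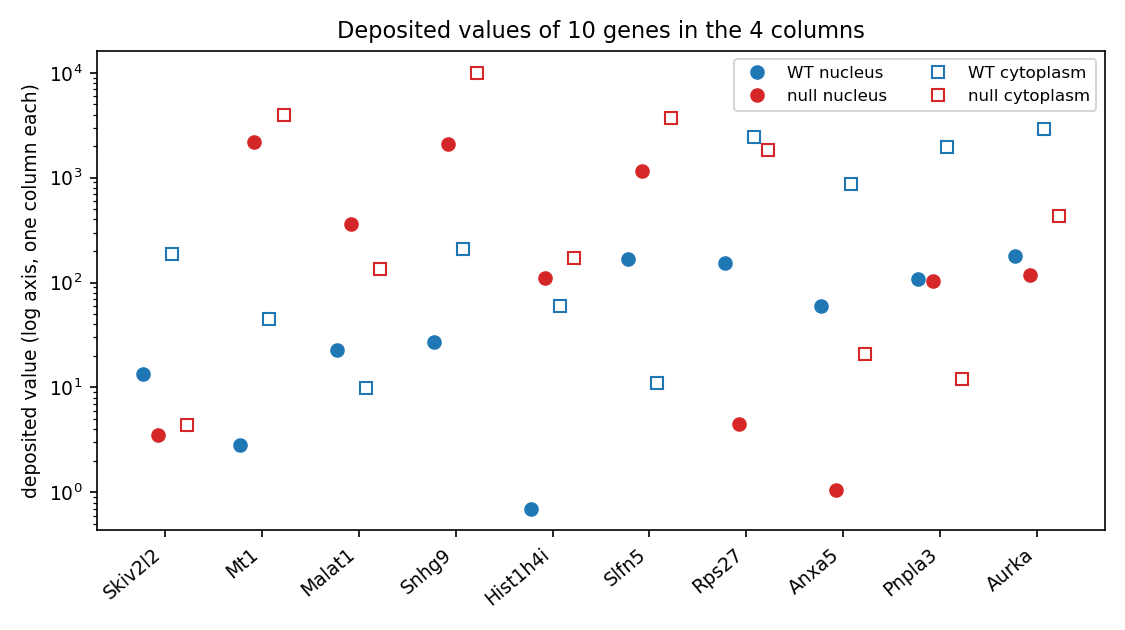
Deposited values of 10 named genes in the 4 columns on a log axis, 1 column each with no replicates. Filled circles are nuclei, open squares cytoplasms, blue WT and red null. Skiv2l2 has 13.3 and 3.54 in the nuclei, and Mt1 has 2.82 and 2208.

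By RefSeq gene type, 454 of 791 long noncoding RNA genes were at least 2-fold higher in the null nucleus relative to the median gene and 85 were lower (554 and 25 as deposited). In the cytoplasm 375 were higher and 86 lower (304 and 199 as deposited). Of 13057 protein-coding genes, 3058 were higher and 2149 lower in the nucleus (5825 and 471 as deposited). Of 1900 provisional symbols, 781 were higher and 265 lower in the nucleus (1075 and 89 as deposited). Comparisons of day 21 with day 14, and of age effects with genotype effects, could not be made from these columns.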

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

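All tests in this part were chosen after the results were seen, the B2 stretch was found from the gene set it is tested on, and some first tests were replaced. These were a carry-over test on small RNA genes that left the question undecided, a test for a few large genes that could not have told, a test of the column factors on the nuclear total alone, which they had met, matching on the mean of all 4 columns, which holds the null values, and a comparison of antisense B2 carriers with lists not limited to low WT cytoplasm values, above which the carriers lay. No difference between the compartments could be tested, since each rests on 1 column per genotype. As deposited, null and WT differed in opposite directions in the 2 compartments: the median gene had a log2 difference of 0.91 in the nucleus and -0.79 in the cytoplasm. At least 2-fold higher in the nucleus and at least 2-fold lower in the cytoplasm were 1389 genes, against 16 genes the other way. After median-ratio rescaling these counts were 63 and 74. Of 23 fixed lists, 20 had medians of opposite sign as deposited and 4 after rescaling.

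The lists with opposite relative medians were MTR4 partners (-0.17 in the nucleus and 0.24 in the cytoplasm), chromatin modifiers (-0.25 and 0.16), spliceosome genes (-0.073 and 0.20) and granulosa markers (-0.40 and 0.23). Named genes at least 2-fold apart in opposite directions were Eif3j (-1.01 in the nucleus and 5.54 in the cytoplasm), Igfbp5 (-1.22 and 3.76), Pnmt (-4.03 and 4.59) and Wdfy1 (1.35 and -2.78). These differences were not tested.

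The opposite shift of the median gene was weighed first. A few genes taking a larger part of a column cannot account for it in the nucleus: the top 100 genes held 35.1% of the WT and 43.0% of the null total, which at a fixed total would leave the other genes at 0.878-fold, while the median gene was at 2.22-fold. Round factors applied to the columns before deposit could account for it, but the digits do not decide. With the factors read from them divided out, the null total was 0.588 of the WT total in the nucleus and 0.906 in the cytoplasm. The median gene then had -0.77 and 0.15. If the WT cytoplasm factor was 0.5, which its digits hardly tell from 1, the median gene had -0.77 and -0.81. The 2 cytoplasm factors are then equal, so the ratio of cytoplasm totals stays as deposited, 0.453. The same ratio holds if both factors were 1, which the null cytoplasm digits allow if that column is a mean of 2 values. The factors are known only up to a power of 10 and only if no column is a mean of more than 2 values, which was not examined. Whether they stand for a measured amount of RNA is not given in the sources used here. A real difference in RNA content with genotype or with day stays open and was not tested.

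The set of 303 genes at least 4-fold higher in the WT nucleus than in the WT cytoplasm, relative to the median gene, was weighed second. Small RNA genes and genes under 5 in the WT nucleus are not in it. The set's relative median was 2.03 in the null nucleus against the WT nucleus, and 4.36 in the cytoplasm, a value raised by choosing the genes for low WT cytoplasm values. Chance low values in that column cannot make the nuclear median, which leaves it out. That median lay above 0.61, the percentile 97.5 of lists matched on the WT cytoplasm value. Of 81 abundant members with a null cytoplasm value above 0, 3 had under 10% of their null nuclear value there, Pola2 lowest at 3.22%. The median share was 84.8%. Carry-over of nuclear RNA in a fixed proportion would not leave these 3 so low. Carry-over that differs between RNAs was not excluded, and the null cytoplasm column may hold 1 library. Reads of the B2 repeat could add to genes that hold a copy, since the stretch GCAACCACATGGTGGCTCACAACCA was found in 93 of 290 members with a sequence, against at most 24 for the most shared stretch in 30 random sets, but the carriers do not decide it: the nuclear median was 1.61 for 153 in sense and 0.33 for 160 in antisense, and outside the set 0.27 (92 genes, bootstrap interval 0.0069 to 0.90, percentile 97.5 of random lists 0.25) and 0.016 (128 genes, within its random lists). Under a limit of 60 in the WT cytoplasm, chosen after these values were seen, the nuclear median was 2.15 in sense and 1.87 in antisense. Outside the set it was 1.61 in sense (37 genes, bootstrap interval 1.13 to 2.15) and 1.30 in antisense (37 genes, 0.54 to 1.96). Lists of non-carriers with WT cytoplasm values as low had medians of 0.52 and 0.58, and percentiles 97.5 of 1.09 and 1.13. B2 reads and retained nuclear transcripts cannot be told apart for members with the stretch, nor for those without it (median 1.76), since diverged copies were not searched, and genotype and day stay open.

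The higher values of long noncoding RNA genes in both null columns, relative to the median gene, were weighed last. The tables argue against low expression in the WT columns as the whole cause: the medians of 1.32 in the nucleus and 0.89 in the cytoplasm lay above 0.69 and 0.65, the percentiles 97.5 of lists matched on both WT columns, but those lists had medians of 0.56 and 0.55, so a large part goes with low WT values. Transcript length does not account for the rest, with 1.29 for the 724 genes that could be matched, against 0.66 at the percentile 97.5 of lists matched on length and WT mean. Without carriers of the exact B2 stretch the median was 1.25, so they are not the whole cause, but diverged copies were not searched. Loss of MTR4, which feeds such RNAs to the exosome, is a biological explanation that these columns leave open beside the day of the WT oocytes and the processing by the authors.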

How the results depend on the processing

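No paired analysis was possible because the columns carry no replicate numbers. The planned fits with robust moderation, with only the compared groups, with a replicate block, without each library in turn and with an estimated correlation were not run, since there is 1 column per group, and read depth is unknown. Of the counts of genes at least 2-fold apart, those for null against WT stayed within 1.5 times of the main count under a pseudocount of 0.1, no filter, a mean of at least 5, both rescalings, and 4 alternatives chosen after seeing the data (without small RNA genes, without genes with the B2 stretch, and with the column factors divided out, taking 1 or 0.5 for the WT cytoplasm). The direction did not: with the factors divided out and 1 for the WT cytoplasm 2193 genes were higher and 6152 lower in the null nucleus, 4152 higher and 2609 lower in the cytoplasm, and 784 higher and 6453 lower for the difference of differences. With 0.5 these were 2233 and 6325 in the cytoplasm and 2736 and 2488 for the difference of differences, a count of 5224. For nucleus against cytoplasm in WT the count was 13238 as deposited, 2447 after median-ratio rescaling, 2301 after quantile normalization and 5839 with the factors divided out and 1 for the WT cytoplasm. In null it was 10650, then 3029 and 3196 after the rescalings, and for the difference of these differences 10677, then 4586 and 4491. The lower counts after median-ratio rescaling and quantile normalization follow from their construction, which centres the columns on each other. Dividing out the factors does not centre them. The number of lists outside the percentiles on the deposited scale was 7 and 5 for null against WT in nucleus and cytoplasm, 10 and 4 for the compartments in WT and null, and 4 for the difference of differences, and stayed within 1.5 times of these under the alternatives run for lists, except for 4 in the nucleus with the factors divided out and 0.5 for the WT cytoplasm. Taking 1 there gave 5 from the same nuclear values, so at least 1 list depends on the random draw. These alternatives left out the removals of small RNA genes and of B2 carriers. Dividing a column by a constant moves a list and its random lists alike, apart from the effect of the added 1. Stable list counts under median-ratio rescaling or the column factors are therefore no check of the lists.

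Of 127 named gene values, 4 that were at least 2-fold apart as deposited turned from lower to higher under both rescalings, and no other such value changed sign under a pseudocount of 0.1, a mean of at least 5 or the rescalings. These were for nucleus against cytoplasm in WT, with values after median-ratio rescaling and quantile normalization: Pabpn1 (1.33 and 1.22), Hnrnpu (1.39 and 1.36), Lsm14b (1.20 and 1.21) and Suz12 (1.06 and 1.02).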

Other observations

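All tests in this part, and the genes named in it, were chosen after the values were seen. Protein-coding genes with few exons had higher values in the null columns relative to the median gene, which is no statement on their absolute values. Genes whose longest transcript has 1 exon (332 genes) had a relative median log2 difference of 0.98 in the nucleus and 1.09 in the cytoplasm, genes with 2 exons (648) had 0.41 and 0.66, genes with 3 exons (865) had 0.16 and 0.27, and genes with 4 to 10 exons (5909) had -0.035 and -0.016. Without histone genes the 293 single-exon genes had 0.97 and 1.098. The hypothesis that intron-poor transcripts are higher in the null columns, relative to others, whatever their length and expression may hold here: the cytoplasmic median of 1.09 lay above 0.53, the percentile 97.5 of lists matched on length and on the mean of the WT columns, and the nuclear median of 0.98 above 0.70. Those lists had medians of 0.39 and 0.48, so a part goes with low WT values. It was found and tested on the same columns, and the day of the WT oocytes stays open.

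Some genes of the interferon response had higher cytoplasmic values in null than in WT, such as Irf9 (0.711 and 605), Xaf1 (18.6 and 892) and Bst2 (45.1 and 255). All 3 belong to the set of 303 genes chosen as at least 4-fold higher in the WT nucleus than in the WT cytoplasm, and Xaf1 holds the B2 stretch. An interferon response in the null oocytes could be a reason. However, a list of 25 measured interferon-stimulated genes, written after these values were seen, lay at percentile 64.6 in the cytoplasm and 98.6 in the nucleus. Its random lists were matched on the mean of all 4 columns, which holds the null values. In the cytoplasm 9 genes of the list were higher and 3 lower. Mx1 had 6.73 and 3.49. The list does not decide the question.

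Of 8 listed genes of the Oas1 family of 2'-5' oligoadenylate synthetases, 7 were kept, and all 7 were at least 2-fold lower in the null cytoplasm relative to the median gene, with log2 differences from -1.05 to -5.94. In the nucleus 4 of 7 were lower on that scale, but as deposited 1 was lower and 1 higher. The relative cytoplasmic difference was -2.14 for Oas1d (14891 in WT and 1807 in null), -3.13 for Oas1h (9841 and 597), -1.57 for Oas1c (8331 and 1496) and -1.34 for Oas1e (17112 and 3609). The family was picked after its values were seen and was not set against random lists, and its sequences are close, so reads can be split between its genes.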
